A study of Mus musculus with 18 samples.

How the data were processed

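Polyadenylated RNA from 18 mouse brain tissue samples was sequenced. Per the labels, adult male C57Bl6 mice of 8 to 10 weeks received 50 mg/kg Rose Bengal and a 525 nm laser at 125 mW over a 3 mm lesion, tissue was dissected 7 days after injury with the help of TTC, a stain that leaves dead tissue pale, and libraries were made with an MGIEasy stLFR kit, a kit for DNBSEQ sequencers that tags long fragments. Groups were taken from the sample labels: wild type or Trem2 knockout, each with contralateral, peri-infarct and infarct core tissue, and 3 libraries per group. The labels number the libraries of a group but do not say that a number stands for a separate animal or for 1 animal across regions, so p-values measure only the spread between these samples, which may be partly technical. Libraries with the same number deviated together from their group means in wild-type contralateral and peri-infarct tissue (correlations of 0.398, 0.436 and 0.386, each highest with its own number). This pairing comes from the values, as no label states it. Same-numbered wild-type and knockout contralateral libraries, which cannot be 1 animal, correlated at 0.318, 0.355 and -0.135. A shared number need therefore not mark 1 animal, and a batch that follows the number was not tested. A comparison of 3 against 3 by permutation cannot give a 2-sided p under 0.1.

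The authors deposited a table of expected counts per gene and a table of TPM (transcript abundances scaled to a fixed total) for 18922 genes. The deposited expected counts are estimated counts that need not be whole, and 3678 genes (19.4%) had a value that was not whole, so they were rounded to whole numbers before any test. The tests fixed in advance had assumed whole counts, and the same tests were used after rounding. The deposited TPM values are scaled by the authors to transcript length and library, and were used only for alternatives. The submitters' processing notes name HISAT2 2.0.4, Bowtie2, Subread and the mouse genome GRCm39 (mm39), without saying which made which values, and the tool that estimated the counts is not given in the sources used here. Estimated counts can split reads between near-identical genes, so members of multigene families such as H2-T24, Lilr4b and the Oas genes are uncertain, as are overlapping genes, since no use of strand is stated. All sample columns of both tables were used.

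Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalization, robust quasi-likelihood fit) with a mean for each of the 6 groups. This leaves each gene 12 residual degrees of freedom for a spread that its 6 groups share. Of the genes 15329 passed the filter and were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 12 comparisons were knockout against wild type in each of the 3 regions, the regional comparisons within each genotype, and the differences between genotypes of those responses. Samples, comparisons, tests, 39 gene lists, naming rule and most alternatives were fixed before the data were examined.

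Gene lists for cell types and processes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list. Only 1 list call of all comparisons held with an estimated correlation. Of the 39 lists 37 had at least 3 tested members. B cell markers (2 tested members) and mitochondrially encoded genes (0 in the table) were not tested, and 22 listed genes were not in the table. A list score is the mean over members of log2 CPM centred on the mean of all libraries. Scores were compared between genotypes by exact 2-sided permutation of labels within regions, which treats the regions as separate samples. If 1 number of a genotype were 1 animal, 20 arrangements would remain and permutation could not give a p under 0.1, and this was computed as an addition after the data were examined.

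The genes named in the text followed a rule. It takes Trem2, then, among genes called with a mean log2 CPM of at least 1, a proper symbol and no overlap between the libraries of the groups, the 6 largest rises and 6 largest falls, or the 5 smallest p values where none passed. It then takes 3 members with the smallest p of each list that shifted, or 2 where these would exceed 30 genes, and 2 members of the microglial lists even where they did not shift, and in genotype comparisons the called neighbours of Trem2. The text gives the first part in full and those members that belong to the lists it describes, except 1 gene that is not reported here. After the data were examined the rule was also applied to the fit without the wild-type core library of replicate 3 and to the mean genotype difference over regions, which was itself added then. The condition of no overlap was applied only to comparisons of 2 groups, so not to that mean. For gene order along the chromosomes a RefSeq gene table of assembly GRCm38.p6 was used, which differs from the submitters' build. Only neighbourhood was taken from it, no coordinates are given, and 15251 of the tested genes matched by gene ID.

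Total counts were between 16993978 and 18713770 per library, so depth differed little. The 18 pairs of replicates within groups differed by more than sampling noise (chi-square per gene from 9.24 to 573), and none was treated as a duplicate. The procedure was tested on simulated counts with 200 changed genes. With all libraries it recovered 38% of 2-fold and 81% of 4-fold changes between genotypes in contralateral tissue, 40% and 80% in the peri-infarct tissue, 40% and 80% in the core, and 74% and 93% for the mean over regions. Without the wild-type core library of replicate 3 the shares were 86% and 96%, 84% and 96%, 80% and 95%, and 93% and 99%. Among unchanged genes 2, 3, 8 and 8 were called with all libraries and 13, 8, 6 and 9 without that library. Every simulated library had the spread fitted over all groups, which that library widens. The real spread is uneven between libraries, so the shares with all libraries need not hold for the real data.

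The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, no filter on low counts, a minimum absolute log2 fold change of 1, only the libraries of the groups compared, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) and with a minimum TPM of 1 in 3 libraries, the replicate number as a block, and each library left out in turn. Added after the data were examined were the omission of the wild-type core library of replicate 3 from every comparison (15432 genes tested), limma-voom with sample quality weights, and that omission together with DESeq2 or with only the groups compared. DESeq2 left the adjusted p of 303 genes in the contralateral genotype comparison open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.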

Results

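Adult male C57Bl6 mice, wild type or lacking Trem2, received a photothrombotic stroke, in which laser light activates the injected dye Rose Bengal in cortical vessels and closes them. Tissue was collected 7 days later from the infarct core, from the peri-infarct tissue around it and from the contralateral side. Trem2 is a lipid-sensing receptor of microglia and macrophages, and the design asks how its loss alters expression in each region and how it alters the response to the lesion. The 2 genotypes and 3 regions make 6 groups of 3 libraries, 18 libraries in all. The total count per library ranged from 16993978 to 17691801 in 17 libraries and was 18713770 in the wild-type core library of replicate 3. Values given after gene names are log2 fold changes ± SE with 3 libraries per group, tested with edgeR's quasi-likelihood test and adjusted by Benjamini-Hochberg over 15329 genes. The SE was derived from that test, as the absolute log2 fold change divided by the square root of its F statistic.

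The wild-type core library of replicate 3 stood apart from the others. It held 16216 detected genes against 16720 to 17109 elsewhere, and its 10 most abundant genes took 15.5% of its counts against 3.27% to 5.38%. On the first principal component, which carried 69.6% of the variance of log2 CPM, it lay at 254 while the other core libraries lay between 27.3 and 58.8. Its mean score for excitatory cortical neuron markers was -6.84, against -0.376 to 0.421 in the other 5 core libraries, and its score for disease-associated microglia, the state of microglia around plaques and dead cells, was 3.25 against 0.922 to 1.42. It also widened the spread that all groups share in the fit. Each comparison is therefore also given without it, an addition made after the data were examined.

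**Figure D1:**
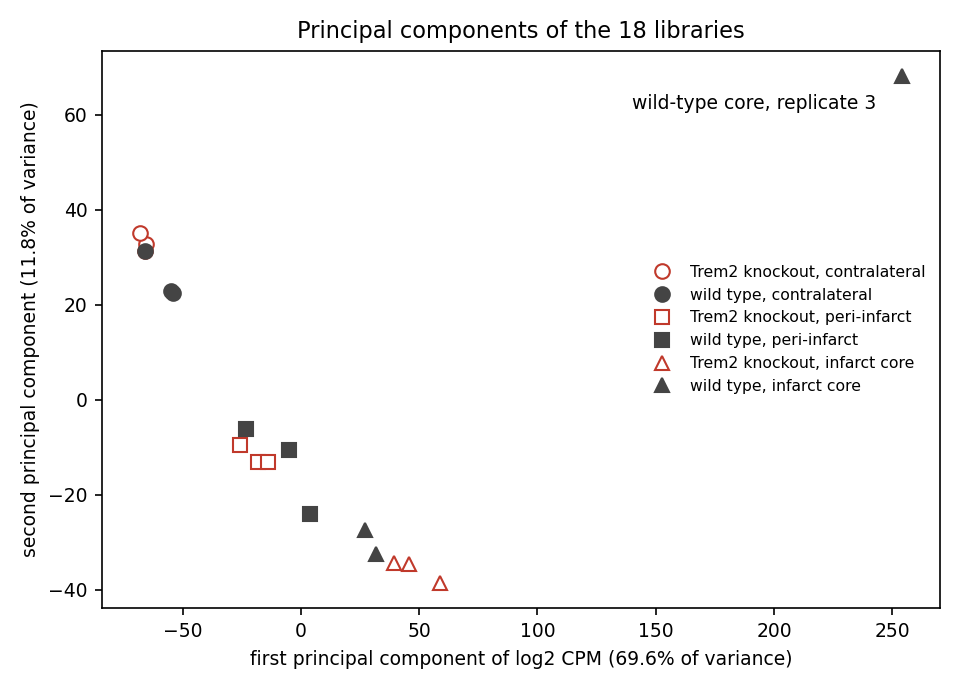
First principal component (x axis, 69.6% of variance) against the second (y axis, 11.8%) of log2 CPM for the 18 libraries, 1 point each. Filled grey points are wild type, open red points knockout, with circles for contralateral, squares for peri-infarct and triangles for core. The wild-type core library of replicate 3 lies at 254 and the other 5 core libraries between 27.3 and 58.8.

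Trem2 itself was measured first, as a check of the labels. Wild-type tissue held 25.5 ± 4.27 CPM (SD, n = 3) on the contralateral side, 116 ± 21 in the peri-infarct tissue and 440 ± 416 in the core, where the library that stood apart set the spread. Knockout tissue held 0.643 ± 0.285, 3.2 ± 0.729 and 6.35 ± 1.64 CPM, which is 2.52%, 2.76% and 1.44% of the wild-type means. Without the library that stood apart the wild-type core mean was 200 CPM (184 and 215, n = 2) and the knockout share 3.18%. Trem2 was lower in every knockout library than in every wild-type library of its region (9 of 9), with a mean log2 difference of -5.33 (2-sided exact permutation within regions, p = 0.00025, the smallest that 8000 arrangements can give). Per region, Trem2 fell by 5.29 ± 0.62 (edgeR adjusted p = 0.011), 5.17 ± 0.58 (0.0062) and 6.11 ± 0.60 (0.0012). Without the library that stood apart, the difference in the core was -4.95 ± 0.23.

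**Figure D2:**
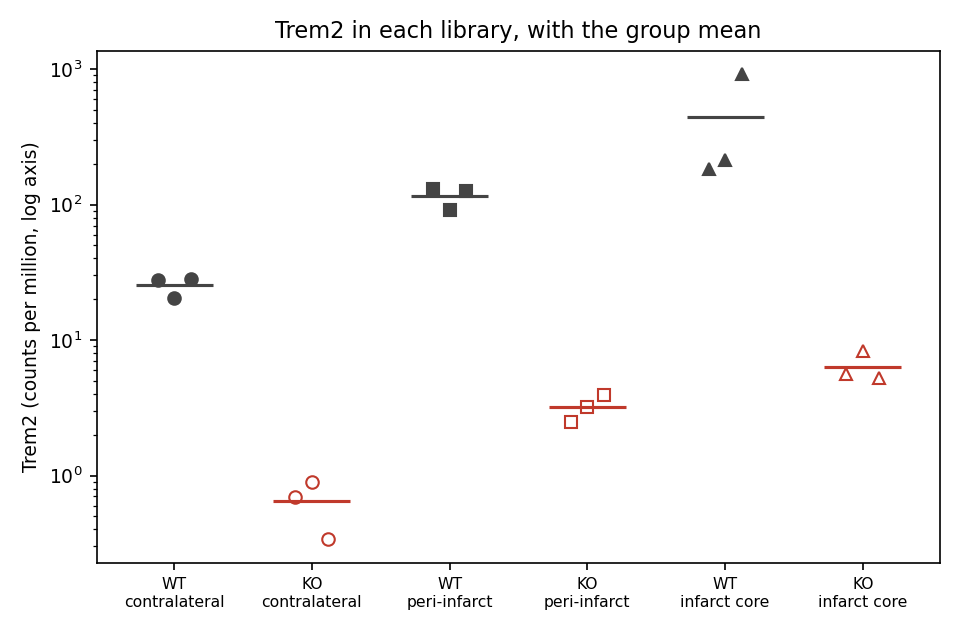
Trem2 in CPM (counts scaled to library size, y axis, log scale) in each of the 18 libraries by genotype and region, with 1 point per library and a line at the group mean. Wild-type means were 25.5, 116 and 440 and knockout means 0.643, 3.2 and 6.35 CPM.

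Peri-infarct against contralateral tissue in wild-type mice measured the response at the border of the lesion, and macrophage genes were among the largest rises. Mmp12, a macrophage elastase, rose by 6.49 ± 1.13 (adjusted p = 0.022) and Cd244a, a receptor of the SLAM family, by 4.16 ± 0.94. The scavenger receptors Msr1 and Cd36 rose by 4.06 ± 0.77 and 4.05 ± 0.99, Gpnmb, a glycoprotein of lipid-laden macrophages, by 4.0 ± 0.80 and Rgs1, a leukocyte regulator of G-protein signalling, by 3.97 ± 0.76. Trem2 rose by 2.18 ± 0.50 (0.033). In all, 501 genes rose and 1 fell, Ap1s3, a subunit of a vesicle adaptor, at -0.80 ± 0.20 (0.042).

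Of 18 cell cycle genes 13 rose, and 17 when adjusted over the list alone, among them the proliferation marker Mki67 (2.83 ± 0.47) and the kinetochore gene Cenpf (2.23 ± 0.37). The list shifted up with a camera adjusted p = 1.3e-21, and an adjusted p = 0.18 with an estimated correlation. Of 25 disease-associated microglia genes 14 rose (21 adjusted over the list alone), with the lysosomal glycoprotein Cd68 at 3.12 ± 0.57 and the protease inhibitor Cst7 at 2.28 ± 0.41 (camera adjusted p = 2.4e-21, and adjusted p = 0.18 with an estimated correlation). Homeostatic microglia genes rose too, 8 of 16 (12 adjusted over the list alone), with the receptors P2ry13 (1.14 ± 0.21) and Gpr34 (1.46 ± 0.27), and an adjusted p = 0.17 with an estimated correlation. Of 21 reactive astrocyte genes 10 rose (17 adjusted over the list alone), led by the cytokine receptor Osmr (1.23 ± 0.15) and the serpin Serpina3n (1.84 ± 0.25), with an adjusted p = 0.083 under an estimated correlation. Complement (9 of 15, with C1qa at 2.21 ± 0.41), interferon response (9 of 19, with the antiviral tether Bst2 at 2.11 ± 0.45) and phagocytosis and lysosome genes (14 of 25) rose, or 12, 17 and 22 adjusted over the list alone, each with an adjusted p = 0.18 under an estimated correlation. Cholesterol synthesis genes shifted down as a list (median -0.44, camera adjusted p = 6.4e-10, and adjusted p = 0.19 with an estimated correlation) with 0 of 18 members passing. Without the library that stood apart, 16 of the 18 fell.

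The number of calls in this comparison rested on single libraries. Leaving out wild-type contralateral replicate 1, 2 or 3 gave 1, 0 and 4 genes, leaving out peri-infarct replicate 1, 2 or 3 gave 18, 368 and 0, and leaving out the core library of replicate 3 gave 3016, of which 2192 were higher and 824 lower and which included all 502. Where edgeR called 0 genes, 1517 and 1590 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 812 and 164 genes with all libraries.

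In the wild-type core against contralateral tissue, 4456 genes rose and 1770 fell by edgeR, while limma-trend on log2(TPM + 1) called 3118 higher and 6274 lower. Fitted with only the 6 libraries compared, edgeR called 0 genes, with 3556 at an unadjusted p under 0.05, while DESeq2 and limma-voom called 7668 and 7527 with all libraries. The largest rises were in Mmp12 (9.52 ± 1.27, adjusted p = 0.00013), the collagenase Mmp13 (8.07 ± 1.29), Cd36 (7.04 ± 1.12), Rgs1 (6.69 ± 0.83), Arg1, an arginase of alternatively activated macrophages (6.66 ± 1.40), and the fibrillar collagen Col3a1 (6.63 ± 1.16). The largest falls were in neuronal genes, the dopamine receptor Drd2 (-4.22 ± 1.03, adjusted p = 0.0057), Syndig1l (-3.25 ± 0.83), the tachykinin receptor Tacr1 (-3.14 ± 0.90), Klhl1 (-2.84 ± 1.03), the synaptotagmin Syt2 (-2.82 ± 0.88) and Tac1, which encodes substance P (-2.52 ± 0.82). Drd2 is also a striatal marker, and the 8 striatal markers shifted down together (median -1.92, camera adjusted p = 0.0071, and adjusted p = 0.45 with an estimated correlation). Trem2 rose by 4.11 ± 0.54.

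Whole gene groups moved in the wild-type core. All 20 fibrotic scar and matrix genes, all 18 cell cycle genes and all 19 interferon response genes rose, with the same counts adjusted over the list alone. Of 25 members each, 24 disease-associated microglia genes and 24 phagocytosis and lysosome genes rose, also adjusted over the list alone, with Cd68 at 5.34 ± 0.63 and Grn, the lysosomal growth factor progranulin, at 4.12 ± 0.48. Of 20 lipid uptake, storage and efflux genes 17 rose (18 adjusted over the list alone), among them the lipase Lpl (4.51 ± 0.53) and the cholesterol exporter Abca1 (3.44 ± 0.41). Cholesterol synthesis went the other way, with 16 of 18 genes lower (17 adjusted over the list alone) and Stard4, a sterol carrier, at -1.04 ± 0.17. Of 37 lists 19 shifted up and 9 down, each with an adjusted p from 0.32 to 0.55 under an estimated correlation. Beside these groups, leaving out the library that stood apart took the median of the disease-associated list from 3.77 to 2.65, of the scar list from 4.09 to 3.16 and of the synaptic list from -1.03 to -0.47. It gave 3639 rises and 2569 falls, and 4985 genes were shared with the fit of all libraries.

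Matrix and neutrophil genes were higher in the wild-type core than in the peri-infarct tissue, in a comparison with 1891 genes higher and 104 lower. Of 20 scar and matrix genes 19 rose, with the same number adjusted over the list alone (median 2.60, camera adjusted p = 2.4e-13, and adjusted p = 0.41 with an estimated correlation). The lysyl oxidase Lox, which cross-links collagen, rose by 3.42 ± 0.93, the collagens Col3a1 and Col1a1 by 3.41 ± 0.99 and 3.40 ± 0.87, Mmp13 by 3.40 ± 0.93, the matrix protein Mgp by 3.24 ± 0.77 and Anxa1, an annexin, by 3.17 ± 0.74 (adjusted p from 0.034 to 0.041). The named falls were Drd2 at -4.37 ± 1.03, the neuropeptide gene Cartpt at -2.16 ± 0.60, the potassium channel subunit Kcnmb2 at -1.79 ± 0.47, Pld5 at -1.74 ± 0.34, Pcp4l1 at -1.52 ± 0.38 and Mme, the peptidase neprilysin, at -1.49 ± 0.39. Excitatory neuron, inhibitory neuron and synaptic lists shifted down (medians -0.70, -0.98 and -0.80, camera adjusted p = 0.0031, 0.0014 and 0.00014, and adjusted p = 0.47, 0.45 and 0.46 with an estimated correlation), as did resting astrocyte genes (-0.56, adjusted p = 0.46 with an estimated correlation). The 8 striatal markers, Drd2 among them, also shifted down (median -1.88, camera adjusted p = 0.0056, and adjusted p = 0.44 with an estimated correlation), but not without peri-infarct replicate 2 (0.067). Their scores in peri-infarct replicates 1, 2 and 3 were -0.905, 1.64 and -0.771. Neutrophil genes rose (6 of 7, and 7 adjusted over the list alone, median 2.89, adjusted p = 0.41 with an estimated correlation), with the calgranulin S100a8 at 4.05 ± 0.89. Without the library that stood apart 828 genes passed, 766 of them among the 1995, and the 6 largest rises had an adjusted p from 0.058 to 0.17. Of the named falls Drd2, Cartpt and Mme then missed the threshold (adjusted p = 0.081, 0.079 and 0.084). So did the excitatory neuron list (median -0.09, camera adjusted p = 0.13) and the resting astrocyte list (-0.13, 0.065), while the inhibitory neuron and synaptic lists passed (-0.41 and -0.20). Leaving out another library gave 98, 0 and 0 genes for peri-infarct replicates 1, 2 and 3 and 5421 and 4713 for core replicates 1 and 2. Fitted with only the 6 libraries compared, edgeR called 0 genes. Where it called 0, 3718, 4206 and 1230 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 3529 and 0 with all libraries.

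In Trem2-knockout mice the border of the lesion responded with reactive astrocyte, complement and phagocyte genes. Peri-infarct against contralateral tissue, 678 genes rose and 8 fell, led by Mmp12 (6.35 ± 1.46), the leukocyte receptor Lilr4b (5.45 ± 1.27), Cd244a (5.04 ± 1.14), the macrophage scavenger protein Cd5l (5.01 ± 1.02), Spp1, the matrix cytokine osteopontin (4.70 ± 0.76, adjusted p = 0.0083), and the acute-phase gene Saa3 (4.56 ± 1.11). The largest of the 8 falls by the naming rule were in Znhit3 (-0.45 ± 0.10), the angiogenic factor Vegfa (-0.41 ± 0.11), Acot13 (-0.37 ± 0.09), the mitochondrial chaperone Timm8b (-0.36 ± 0.09), Ramac (-0.35 ± 0.09) and Tmem70, an assembly factor of ATP synthase (-0.32 ± 0.08). Of 21 reactive astrocyte genes 17 rose, with the same number adjusted over the list alone (camera adjusted p = 6e-23), and this was the 1 list of all comparisons whose shift passed with an estimated correlation (adjusted p = 0.021). Osmr rose by 1.81 ± 0.15 and Serpina3n by 2.80 ± 0.26. Complement genes rose in 13 of 15 cases, also adjusted over the list alone, with C4b at 1.87 ± 0.22 (adjusted p = 0.095 with an estimated correlation). Of 25 disease-associated microglia genes 15 rose (22 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation), with Cst7 at 3.22 ± 0.46 and Clec7a, a receptor for fungal glucans, at 3.54 ± 0.57. Trem2 transcripts that remained rose by 2.30 ± 0.60 (0.046). Leaving out 1 library moved the 686 calls to 82, 56 or 78 for contralateral replicates 1, 2 and 3, to 262, 216 or 161 for peri-infarct replicates 1, 2 and 3, and to 3296 (2121 higher and 1175 lower) for the wild-type core library of replicate 3, which held all 686.

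In the knockout core against contralateral tissue 3016 genes rose and 508 fell. Mmp12 (9.24 ± 1.47), Lilr4b (7.95 ± 1.21), Col3a1 (7.51 ± 1.21), Arg1 (7.44 ± 1.59), Mmp13 (7.29 ± 1.32) and Cd5l (7.19 ± 1.12) rose most. The falls held Drd2 (-2.73 ± 0.87), Clic6, a chloride channel of the choroid plexus (-3.78 ± 1.27), the cilium genes Drc7 (-3.12 ± 1.03), Cfap65 (-2.61 ± 0.79) and Ttc21a (-2.36 ± 0.80), and Vwa5b1 (-2.35 ± 0.65). Choroid plexus markers varied among the contralateral knockout libraries (mean score 1.04 ± 2.54, SD, n = 3). Of 20 scar genes 19 rose (20 adjusted over the list alone), of 25 disease-associated microglia genes 23 rose (the same adjusted over the list alone) and of 18 cholesterol synthesis genes 16 fell (18 adjusted over the list alone), each with an adjusted p = 0.17 under an estimated correlation. Osmr rose by 2.63 ± 0.16 (1.5e-06). Without the wild-type core library of replicate 3, 8854 genes passed, 4562 higher and 4292 lower, and included all 3524.

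Between core and peri-infarct tissue of the knockout edgeR called 0 genes, while 2857 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 895 and 25. Among genes past the naming rule's expression limit, the 5 smallest p values belonged to matrix and fibroblast genes and did not pass (adjusted p = 0.059 each): Ccdc80 (0.97 ± 0.14), the metalloprotease Adam12 (2.47 ± 0.37), the collagens Col4a1 (1.69 ± 0.27) and Col5a1 (2.27 ± 0.38) and the transcription factor Hic1 (2.09 ± 0.34). The scar list shifted up (median 2.64, 19 of 20 higher adjusted over the list alone, camera adjusted p = 7.9e-20, and adjusted p = 0.31 with an estimated correlation). Choroid plexus and striatal markers shifted down (medians -3.73 and -2.00, adjusted p = 0.4 and 0.31 with an estimated correlation), the former not without peri-infarct knockout replicate 3 (camera adjusted p = 0.067). Without the wild-type core library of replicate 3, which is in neither group but sets the shared spread, 6190 genes passed, 3752 higher and 2438 lower.

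The responses of the genotypes were correlated across genes. For peri-infarct against contralateral tissue the log2 fold changes had a Pearson r of 0.815 and a Spearman rho of 0.744 across 15329 genes, which are not independent replicates. Of 502 genes called in the wild type and 686 in the knockout 380 were shared, all in the same direction, where independent lists would share 22.5. Of these calls 501 and 678 were rises, so the shared direction says little. For the core against contralateral tissue r was 0.9 and rho 0.908, and 3102 of 6226 and 3524 genes were shared, all in the same direction, where independent lists would share 1430. With wild-type core replicate 3 left out, the shared genes numbered 2136 at the border and 5690 in the core, again all in the same direction, where independent lists would share 644 and 3560. Both responses come from 1 fit with a common spread per gene, which can itself raise the number shared above that of independent lists.

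In the contralateral tissue, the genotype comparison gave 1 gene, Trem2. Disease-associated microglia genes were lower in the knockout as a list. Of 25 disease-associated microglia genes 0 passed over all genes in edgeR and 3 were lower adjusted over the list alone, the median was -0.69 and the list shifted down (camera adjusted p = 6.8e-13, and adjusted p = 0.69 with an estimated correlation). Clec7a was at -2.51 ± 0.55 (adjusted p = 0.82) and Cst7 at -1.93 ± 0.46 (1). The lists of phagocytosis and lysosome (median -0.30, with the protease Ctsd at -0.90 ± 0.49), lipid handling (-0.27, with Msr1 at -1.85 ± 0.79) and reactive astrocytes (-0.54, with Osmr at -0.54 ± 0.15) also shifted down. Interferon response genes shifted up (0.37, with Oasl2 at 0.76 ± 0.39). Each of these 4 lists had 0 members adjusted over the list alone and an adjusted p = 0.69 with an estimated correlation. The homeostatic microglia list did not pass, with Fcrls at -0.54 ± 0.42 and the growth factor receptor Csf1r at -0.29 ± 0.27. In the same libraries choroid plexus markers were higher in the knockout by a median of 2.49 and striatal markers by 0.74, also with an adjusted p = 0.69 under an estimated correlation. With any 1 of the 6 libraries left out the disease-associated, lipid handling and reactive astrocyte lists passed. The phagocytosis and lysosome list did not without knockout replicate 3 (camera adjusted p = 0.064), nor did the interferon list without knockout replicate 3 (0.61) or wild-type replicate 2 (0.12). The choroid plexus list did not pass without knockout replicate 2 (0.87), wild-type replicate 1 (0.062) or the core library that stood apart (0.055), nor the striatal list without replicate 1 of the knockout (0.11) or of the wild type (0.36).

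Among genes past the expression limit of the naming rule, the smallest p values below Trem2 in contralateral tissue were those of Nnt, the proton-pumping transhydrogenase of mitochondria (-0.81 ± 0.14, adjusted p = 0.27), of the telomere gene Pot1b (-0.80 ± 0.15), Mmut, methylmalonyl-CoA mutase (0.67 ± 0.13), the folate enzyme Aldh1l2 (-0.59 ± 0.12) and Glo1, which detoxifies methylglyoxal (1.02 ± 0.22, 0.78). Without the wild-type core library of replicate 3, 6 genes passed, and by the same naming rule Glo1 (1.04 ± 0.17, adjusted p = 0.047) and Mmut (0.69 ± 0.08) rose and Clec7a (-2.48 ± 0.36, 0.025) and Nnt (-0.79 ± 0.12, 0.025) fell beside Trem2, with 13 disease-associated microglia genes lower adjusted over the list alone. Pot1b, Mmut and Glo1 lie on the chromosome of Trem2, where strain and genotype stay open as causes. With contralateral knockout replicate 1, 2 or 3 left out edgeR called 0 genes, with 337, 401 and 360 at an unadjusted p under 0.05, against 454 with all libraries, where DESeq2 and limma-voom called 14 and 0 genes.

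In the peri-infarct tissue Trem2 was again the 1 gene to pass, and microglial and dividing-cell genes were lower in the knockout as lists while interferon, T and NK cell and myelin genes were higher. The disease-associated microglia list shifted down (median -0.74, 1 of 25 lower adjusted over the list alone, camera adjusted p = 5e-10), as did cell cycle genes (median -0.63, 7.4e-10, with Bub1, a spindle checkpoint kinase, at -1.14 ± 0.47), and interferon response genes shifted up (median 0.61, 1.6e-08, with Xaf1 at 0.69 ± 0.27), each with an adjusted p = 0.58 under an estimated correlation. Lipid handling genes shifted down (median -0.27, 3 of 20 lower adjusted over the list alone, adjusted p = 0.58 with an estimated correlation), with Lpl at -1.90 ± 0.48 (adjusted p = 0.89) and Ch25h, cholesterol 25-hydroxylase, at -2.23 ± 0.58 (1). Phagocytosis and lysosome genes shifted down (median -0.44, adjusted p = 0.67 with an estimated correlation), with Atp6v0d2, a subunit of the proton pump, at -2.05 ± 0.70. The homeostatic list did not pass, with Fcrls at -0.78 ± 0.42. Choroid plexus and striatal markers were higher in the same knockout libraries, by medians of 3.44 and 0.76, each with an adjusted p = 0.58 under an estimated correlation. T and NK cell, oligodendrocyte and myelin, and endothelial lists were higher too (medians 0.87, 0.39 and 0.11, camera adjusted p = 0.0016, 0.0051 and 0.033, and adjusted p = 0.58, 0.79 and 0.58 with an estimated correlation). The T and NK cell list did not pass without knockout replicate 2 (camera adjusted p = 0.086), nor the myelin list without replicate 1 of the knockout (0.075) or of the wild type (0.25). The endothelial list did not without knockout replicate 1 (0.33), wild-type replicate 1 (0.25) or 2 (0.35) or the core library that stood apart (0.066). The other lists named here that shifted did so with any 1 of the 6 libraries left out.

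Under the same limit the smallest p values behind Trem2 in the peri-infarct tissue were those of Nnt (-0.81 ± 0.14, adjusted p = 0.2), the class I histocompatibility gene H2-T24 (1.49 ± 0.26, 0.2), C4b (1.05 ± 0.21), Vegfa (-0.52 ± 0.11) and Mmut (0.60 ± 0.13), and none passed. Without the wild-type core library of replicate 3, 18 genes passed, 6 higher and 12 lower. Mmp12 (-4.68 ± 0.72, adjusted p = 0.028), Ch25h (-2.23 ± 0.33), Lpl (-1.92 ± 0.23, 0.0065), Clec7a (-1.54 ± 0.27), the polymerase gene Polh (-1.02 ± 0.14) and the oxygen sensor Egln3 (-0.96 ± 0.17) fell. H2-T24 (1.47 ± 0.22), C4b (1.04 ± 0.15), Glo1 (0.97 ± 0.17), Tcte3 (0.62 ± 0.11) and Mmut (0.59 ± 0.08) rose. Each of these named rises lies on the chromosome of Trem2, as do Polh and Vegfa among the genes that were lower. Strain and genotype stay open as causes there. In that fit 16 of 25 disease-associated microglia genes and 14 of 18 cell cycle genes were lower adjusted over the list alone. With peri-infarct knockout replicate 1, 2 or 3 left out edgeR called 0 genes, with 376, 451 and 280 at an unadjusted p under 0.05, against 495 with all libraries, where DESeq2 and limma-voom called 17 and 1 genes.

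In the infarct core 2 genes passed, Trem2 and H2-T24 (2.28 ± 0.26, adjusted p = 0.0043), which lies on the chromosome of Trem2. With only the 6 core libraries in the fit edgeR called 0 genes, with 233 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 94 and 2 with all libraries. Hypoxia and glycolysis genes (median -0.68, 12 of 16 lower adjusted over the list alone), disease-associated microglia genes (-1.19, 14 of 25), cell cycle genes (-1.08, 15 of 18) and phagocytosis and lysosome genes (-0.95, 7 of 25) shifted down, and interferon response genes shifted up (0.63, 5 of 19 higher adjusted over the list alone), each with an adjusted p = 0.83 under an estimated correlation. Without wild-type core replicate 1, and with replicate 3 kept, the interferon list missed the threshold (camera adjusted p = 0.061), and its member Oasl1 was at -0.11 ± 0.55. Single members did not pass, with Vegfa at -0.67 ± 0.11 (adjusted p = 0.072), Lpl at -2.36 ± 0.48 (0.22), Ch25h at -2.76 ± 0.57 (0.22), Spp1 at -2.24 ± 0.68 (0.4) and the interferon-induced Ifi44 at 1.79 ± 0.41 (0.26). Of these, Vegfa is among the tested genes nearest to Trem2, where strain and genotype stay open as causes. The excitatory cortical neuron list shifted up by camera although its median was -0.15 and its mean -0.0632. Inhibitory neuron, synaptic, astrocyte and myelin lists shifted up too, and none of these shifts held with an estimated correlation. These neuronal, glial and phagocyte lists are those in which the wild-type core library of replicate 3 stood apart from the other core libraries.

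Without that library the core gave a different picture, with 472 genes called, 154 higher and 318 lower, which included the 2. This fit holds 2 wild-type core libraries. Their scar scores (1.5 and 1.59) lay below the knockout ones (1.94 to 2.65) and their synaptic scores (0.256 and 0.143) above (-0.325 to -0.215). Disease-associated microglia scores overlapped (1.22 and 1.42 against 0.922 to 1.39). Cell cycle scores were higher in the wild type (1.29 and 1.45 against 1.14 to 1.21). The amount of lesion in the pieces and genotype therefore cannot be told apart here. Interferon response genes led: 15 of 19 rose (18 adjusted over the list alone, median 1.45, camera adjusted p = 2.4e-16, and adjusted p = 0.24 with an estimated correlation). The antiviral synthetases Oas3 (2.74 ± 0.60, adjusted p = 0.03) and Oas2 (2.20 ± 0.39, 0.014), their relative Oasl1 (1.93 ± 0.42), the transcription factor Irf7 (2.04 ± 0.43) and Ifi44 (1.93 ± 0.45) were among the named rises. H2-T24 (2.58 ± 0.26) was also among them, and it lies on the chromosome of Trem2, where strain and genotype stay open. Cholesterol synthesis genes fell, 10 of 18 (14 adjusted over the list alone, median -0.41, adjusted p = 0.15 with an estimated correlation), as did 9 of 20 synaptic genes (17 adjusted over the list alone, median -0.43, adjusted p = 0.15 with an estimated correlation). The named falls were Mmp12 (-2.77 ± 0.65), the activity-dependent transcription factor Npas4 (-1.55 ± 0.30), Ch25h (-1.54 ± 0.34), the serotonin receptor Htr2a (-1.49 ± 0.28), Hs3st2 (-1.48 ± 0.32) and Lpl (-1.25 ± 0.24, 0.021). The disease-associated microglia, cell cycle and lipid handling lists did not pass in this fit (camera adjusted p = 0.56, 0.17 and 0.68), and Spp1 was at -0.85 ± 0.47 (0.33). Phagocytosis and lysosome, TREM2 signalling, astrocyte, neuron, synaptic, myelin and clock lists, 8 in all, turned direction between the fits, and 2 of the 14 lists kept their call and direction, interferon response and hypoxia.

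**Figure D3:**
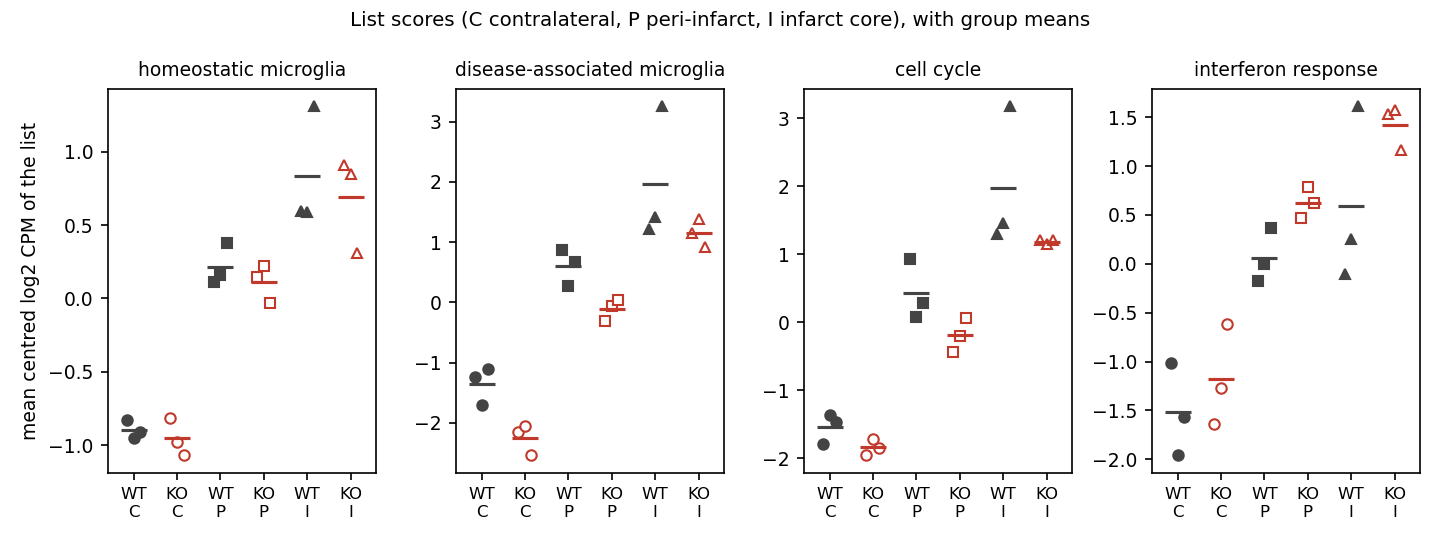
Mean centred log2 CPM (y axis) of 4 gene lists in each of the 18 libraries (points) with group means (lines), wild type filled and knockout open, for contralateral (C), peri-infarct (P) and core (I). The disease-associated microglia score averaged -1.35 and -2.25 in wild-type and knockout contralateral tissue and 0.6 and -0.113 in peri-infarct tissue, and the homeostatic score -0.896 and -0.956, then 0.215 and 0.112.

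Because few genes passed within a region, the mean of the 3 regional genotype differences was tested as 1 contrast of the same fit, a comparison added after the data were examined. Across regions 14 genes were higher and 21 lower in the knockout by edgeR, and 35 higher and 17 lower by limma-trend on log2(TPM + 1). By the naming rule the largest falls were those of Mmp12 by 4.68 ± 0.67 (adjusted p = 0.0095), Spp1 by 2.23 ± 0.39, Ch25h by 2.04 ± 0.35, Clec7a by 1.90 ± 0.30 (0.019), Lpl by 1.53 ± 0.27 and Cst7 by 1.30 ± 0.24. H2-T24 (1.33 ± 0.15), Glo1 (1.07 ± 0.13), Acss3, an acyl-CoA synthetase (0.94 ± 0.16), Plekha4 (0.89 ± 0.14), C4b (0.81 ± 0.12) and Mmut (0.68 ± 0.07, adjusted p = 0.0011) rose. Of these, H2-T24, Glo1, C4b and Mmut lie on the chromosome of Trem2. Of 25 disease-associated microglia genes 4 fell (18 adjusted over the list alone, adjusted p = 0.58 with an estimated correlation), and 14 of 18 cell cycle genes were lower and 9 of 19 interferon response genes higher adjusted over the list alone (each adjusted p = 0.58 with an estimated correlation). Choroid plexus markers were higher by a median of 2.03, with an adjusted p = 0.63 under an estimated correlation. Apart from Trem2, 11 of the 35 genes were among the 200 tested genes nearest to Trem2 in gene order, 9 lay elsewhere on its chromosome and 14 on other chromosomes, among them Nnt (-0.81 ± 0.08). Genes of multigene families such as H2-T24, whose reads can be shared between near-identical copies, are uncertain in this and every comparison.

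**Figure D4:**
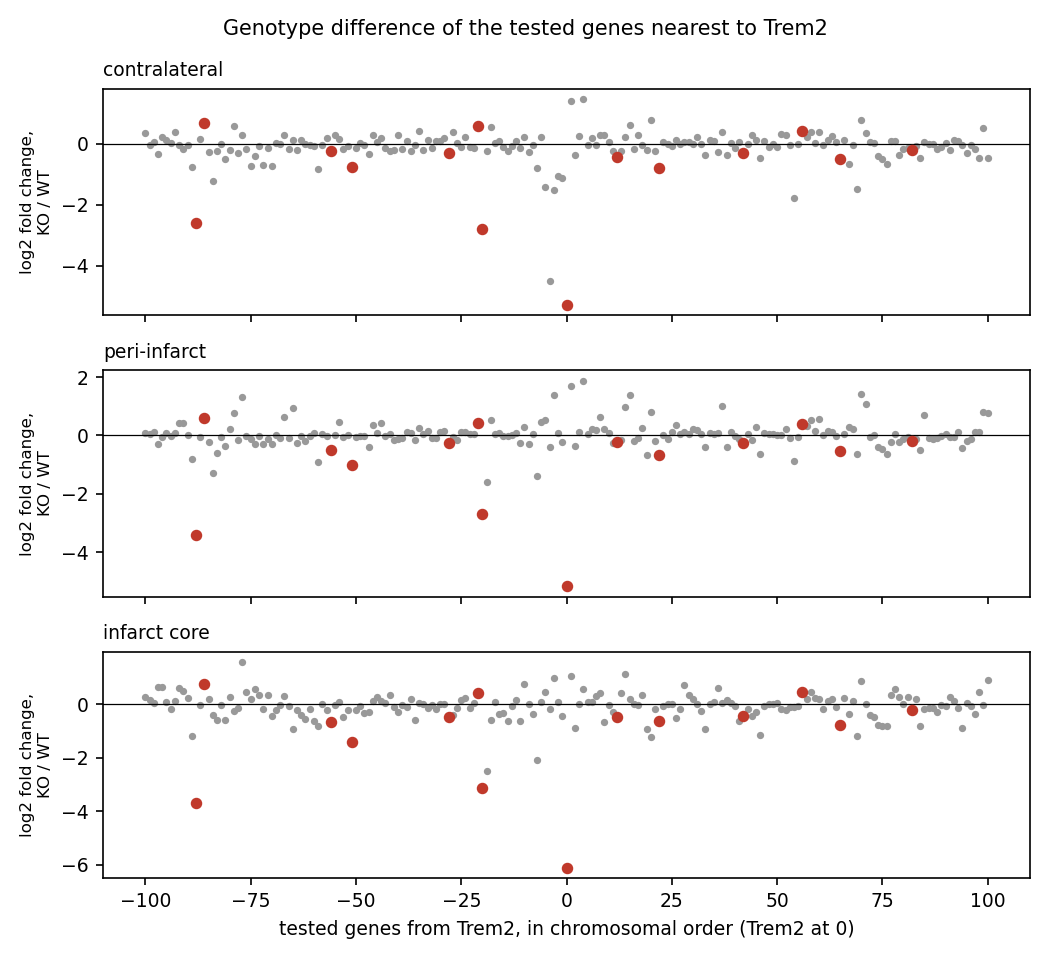
Log2 fold change of knockout against wild type (y axis) for the tested genes nearest to Trem2, by their order along the chromosome (x axis, Trem2 at 0), in each region. Red points are the 13 genes with an unadjusted p under 0.05 and the same direction in all 3 regions, and Trem2.

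Leaving out 1 library changed the 35 calls by more than 1.5 times in most cases. It left 21 and 16 for contralateral knockout replicates 2 and 3, 22, 17 and 13 for contralateral wild-type replicates 1, 2 and 3, 18, 17 and 18 for the peri-infarct knockout replicates, 23 for peri-infarct wild-type replicate 1 and 15, 21 and 16 for the core knockout replicates. It gave 70 without wild-type core replicate 1 and 1151 without replicate 3, where all 35 were kept.

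List scores per library gave the same comparison without a gene-wise model. The disease-associated microglia score was lower in the knockout by 0.809 on average (KO minus WT -0.809, 2-sided exact permutation within regions, p = 0.0005, 0.00617 adjusted over 37 lists). The lipid handling score differed by -0.612 (adjusted permutation p = 0.00617), the hypoxia and glycolysis score by -0.375 (adjusted permutation p = 0.00617) and the cell cycle score by -0.573 (adjusted permutation p = 0.00694). The phagocytosis and lysosome score differed by -0.469 (adjusted permutation p = 0.0722), the interferon score by 0.577 (0.119, permutation) and the striatal score by 1.14 (0.119, permutation), the choroid plexus score by 1.42 (0.254, permutation) and the homeostatic microglia score by -0.101 (0.756, permutation). Without the library that stood apart the disease-associated difference was -0.595 (adjusted permutation p = 0.0116) and the interferon difference 0.747 (adjusted permutation p = 0.0198). The lipid handling difference was then -0.43, hypoxia -0.233 and cell cycle -0.373 (adjusted permutation p = 0.0116 each), and phagocytosis and lysosome -0.266 (0.103, permutation). Cholesterol synthesis moved from -0.0788 to -0.213 and excitatory neurons from 0.462 to -0.34, and both passed (adjusted permutation p = 0.017 and 0.0347). These tests permute each region separately. With the libraries of 1 number moved together over the regions, no score can go below the p = 0.1 that 20 arrangements allow in a permutation.

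Whether the response to the lesion differed between genotypes was tested as the difference of responses. edgeR called 0 genes for peri-infarct against contralateral tissue, core against contralateral tissue and core against peri-infarct tissue, with 112, 366 and 286 genes at an unadjusted p under 0.05. DESeq2 called 0, 1 and 0 and limma-voom 0 in each. Leaving out the library that stood apart, edgeR again called 0 in each, with 517, 1475 and 1963 at an unadjusted p under 0.05. For the border of the lesion the smallest p values by the naming rule included Aldh1l2 (0.65 ± 0.17), and for the core against contralateral tissue H2-T24 (2.05 ± 0.37, adjusted p = 0.98) and Osmr (0.87 ± 0.21), none of which passed. As lists, reactive astrocyte genes rose more in the knockout border (median difference 0.45, camera adjusted p = 2.8e-11, and adjusted p = 0.13 with an estimated correlation) and so did endothelial genes (0.39, adjusted p = 0.13 with an estimated correlation). The mean astrocyte scores were -1.52 ± 0.18 (SD, n = 3) in knockout and -1.07 ± 0.39 in wild-type contralateral tissue and 0.41 ± 0.11 and 0.261 ± 0.21 at the border, where the list did not pass between genotypes (camera adjusted p = 0.12). In the core hypoxia and glycolysis genes rose less (-0.46, camera adjusted p = 4.7e-07, and adjusted p = 0.87 with an estimated correlation). The difference in astrocyte and endothelial genes passed with any 1 of the 12 libraries left out, and that in hypoxia genes did not without the library that stood apart (camera adjusted p = 0.062).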

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

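The tests in this part were chosen after the results were seen, except the counts of other splits of the libraries. Of those, the counts for the mean over regions and for the core without the wild-type library of replicate 3 were added later too. By camera's test of the difference between genotypes, the response to the lesion shifted 15 gene lists for peri-infarct against contralateral tissue, 13 for core against contralateral tissue and 7 for core against peri-infarct tissue. They are given here because the difference between the genotypes was itself tested. None of these shifts held with an estimated correlation. As many lists came from 6, 24 and 25 of 25 splits of the libraries (highest of the others 18, 27 and 27), so chance cannot be excluded. edgeR called 0 genes in each of the 3 differences, with 112, 366 and 286 at an unadjusted p under 0.05, while DESeq2 called 0, 1 and 0 and limma-voom 0 in each. Every split gives at least 0, so the 25 of 25 splits with as many genes (highest of the others 0) say nothing about chance. Without the wild-type core library of replicate 3 the list counts were 15, 17 and 23, of which 14, 3 and 1 were shared in list and direction.

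The wild-type core library of replicate 3 stood apart from the other 5 core libraries. Without its 100 most abundant genes the library lay at 253 on the first principal component (others 25.8 to 57.6). That component rests on 15329 genes after TMM normalization, so leaving out 100 could hardly move it. The test therefore says little about a few genes taking most of the counts. Thinned to 16993978 counts, the lowest total, the library stayed at 254 (others 27.2 to 58.7). Thinning kept 90.8% of its counts and could hardly move it, so this test says little about library depth. A candidate explanation is less brain tissue and more phagocytes in the piece, since 9 of 9 lists lay beyond every other core library in the direction this needs, with synaptic genes at -5.86 (others -0.325 to 0.256) and phagocytosis and lysosome genes at 2.86 (others 0.752 to 1.27). The excitatory neuron and disease-associated microglia lists among the 9 had already set the library apart, so the 9 partly restate that. Such a piece could come from where it was taken or from a larger lesion in that sample, which these tables do not separate. Genotype, which the design names, stays open for the wild-type mean. Of the 3 wild-type core libraries the other 2 lay at 27.3 and 31.6 on the first principal component, near but below the knockout ones (39.2 to 58.8).

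Genes that differed between genotypes in the same direction at an unadjusted p under 0.05 in all 3 regions clustered around Trem2. They made up 6.5% of the 200 nearest tested genes (13) and 0.233% of the others (35 of 15050), which a segment of another strain kept around the targeted gene would give (1-sided Fisher's exact test, p = 2.96e-14), and Guca1b, Mmut, Polh and Vegfa are among them. Of the 35, 6 lay elsewhere on the chromosome of Trem2 (1.1% of 543), all of them higher in the knockout, against 29 on other chromosomes (0.2% of 14507), so such a segment may reach beyond the 200. A response of the tissue to the loss of Trem2 may account for genes on other chromosomes, since of 100 labellings of the libraries the real one alone gave as many outside the neighbourhood (permutation p = 0.01), and the other 99 gave at most 4 on other chromosomes, while with numbers moved together 10 splits are too few for a share under 0.05. Both explanations can hold, strain and genotype stay open for genes on the chromosome of Trem2, and a difference of substrain elsewhere, which Nnt might mark because C57BL/6J mice carry a deletion in it, was not tested.

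The disease-associated microglia list was lower in the knockout, a pattern found and tested on the same libraries. An equal fall of both microglial lists, as fewer microglia alone would give, is argued against only if the regions are separate samples. The list's score minus the homeostatic score was lower in contralateral and peri-infarct tissue (-0.726, 2-sided exact permutation p = 0.005, the smallest that 400 arrangements can give). The homeostatic score itself differed by -0.0815. The test assumes that both scores follow cell number alike. Across wild-type regions their means spanned -1.35 to 1.97 and -0.896 to 0.833. Fewer microglia with more homeostatic transcripts per cell, or fewer dividing cells (cell cycle score -0.573 over the regions), are therefore not excluded. Less lesion tissue in the knockout pieces was not decided. The score minus that of reactive astrocytes was lower over both regions (-0.658, exact permutation p = 0.01). It did not overlap at the border (knockout up to -0.34, wild type from 0.25) but did in contralateral tissue (knockout up to -0.403, wild type from -0.49). Across wild-type regions the mean reactive astrocyte score spanned -1.07 to 0.828, less than the disease-associated one. Less lesion alone could therefore also lower this difference. At the border the mean reactive astrocyte score was 0.41 in the knockout and 0.261 in the wild type. On the first principal component the border libraries lay at -25.8 to -14 in the knockout and -23.4 to 3.95 in the wild type. Both permutation tests move the regions separately, and if a number marks 1 animal each p is 0.1, the smallest of 20 arrangements. The means per number did not overlap (knockout up to -0.678 and wild type from -0.32, then -0.371 and -0.107). That is the outcome which gives this p, so it adds no weight. The same-number correlations of wild-type contralateral and peri-infarct tissue put separate samples in doubt. A microglial state that depends on Trem2 is consistent with the values outside the core: the score minus the homeostatic score did not overlap between genotypes in 3 of 3 regions, but the gap was 0.319 in contralateral tissue, 0.0439 at the border and 0.016 in the core. In the core the list's own score overlapped (knockout up to 1.39, wild type from 1.22) and the list did not pass without the wild-type library of replicate 3 (camera adjusted p = 0.56), strain differences remain open, and so do the higher choroid plexus and striatal markers in the knockout libraries.

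For the mean genotype difference over regions 1 of 25 splits, the real one, gave as many genes (35, highest of the others 1). These splits argue against chance for that count only if the regions were sampled from separate animals. The same-number correlations of wild-type contralateral and peri-infarct tissue (0.398, 0.436 and 0.386) put that condition in doubt. As many lists came from 18 of 25 splits (15, highest of the others 27), so chance cannot be excluded for the list count. If a number marks 1 animal, its libraries move together over the regions, which leaves 10 splits, too few for a share under 0.05 (35 genes, highest of the others 1). A comparison of 3 libraries with 3, or with 2, has 10 splits, too few for a share under 0.05. The real split and the highest of the others called 1 and 0 genes for the genotypes in contralateral tissue, 1 and 0 in peri-infarct tissue, 2 and 0 in the core and 472 and 0 in the core without the library that stood apart. Within the wild type they called 502 and 0 (border against contralateral), 6226 and 0 (core against contralateral) and 1995 and 0 (core against border), and within the knockout 686 and 7, 3524 and 0, and 0 and 0. The lists numbered 15 and 16, 15 and 17, 14 and 25, and 13 and 16 for the genotypes, 22 and 24, 28 and 28, and 27 and 27 within the wild type, and 27 and 23, 25 and 29, and 22 and 22 within the knockout. As many lists as in the real split came from 2, 3, 10 and 5 of the 10 splits for the genotypes, 3, 3 and 2 within the wild type and 1, 4 and 3 within the knockout.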

How the results depend on the processing

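The settings with the wild-type core library of replicate 3 left out of all comparisons or with quality weights were chosen after the data were seen, as were all tests of the mean over regions. The other settings were another tool, scaling, filter, unit, set of libraries or block and each library left out. Counts below follow the order contralateral, peri-infarct and core for the genotypes (1, 1 and 2 genes), then border against contralateral, core against contralateral and core against border in the wild type (502, 6226 and 1995) and the knockout (686, 3524 and 0), then the mean over regions (35). A count is given where it moved by over 1.5 times, and the cause was not tested. Total counts differed little between libraries, and the effect of depth on the counts was not tested.

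DESeq2 called 14, 17 and 94 genes for the genotypes, 812 (border) and 3529 (core against border) in the wild type, 1118 and 895 (border, and core against border) in the knockout and 420 for the mean. It called 1 for the difference of responses of core against contralateral tissue. limma-voom called 0 in contralateral tissue (441 at an unadjusted p under 0.05), 164 and 0 (border, and core against border, with 6390 at an unadjusted p under 0.05) in the wild type, and 294 and 25 in the knockout. DESeq2's size factors in edgeR gave 273 in the wild-type border, and no filter on low counts gave 429 and 39 in the knockout border and core against border. A minimum log2 fold change of 1 left 3045 in the wild-type core, 2212 in the knockout core and 17 for the mean. Only the groups compared gave 2, 2 and 0 for the genotypes, 1950, 0 and 0 in the wild type and 3040, 8384 and 5751 in the knockout, with 233, 3556 and 1230 genes at an unadjusted p under 0.05 where 0 passed. With quality weights in limma-voom the counts were 32, 13 and 298, 2814 in the wild-type border, 3590, 9507 and 6694 in the knockout, and 1680 for the mean. With the wild-type core library of replicate 3 left out DESeq2 called 80, 202, 1027 and 1909 (mean), and only the groups compared 2, 2, 1 and 1151 (mean).

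On log2(TPM + 1) limma-trend called 2 and 20 genes for the genotypes in peri-infarct tissue and core, 929, 9392 and 1042 in the wild type, 1237 and 1414 (border, and core against border) in the knockout and 2 for the difference of responses of core against contralateral tissue. On log2(TPM + 0.1) the counts were 2 in peri-infarct tissue, 1090 and 655 in the wild-type border and core against border, 1441 and 1081 in the knockout, and 1 for that difference. With the TPM minimum they were 2 and 21 for the genotypes, 937 and 1033 in the wild type, 1242 and 1370 in the knockout and 2 for that difference. The wild-type core split into 4456 higher and 1770 lower genes by edgeR, 3118 and 6274 on log2(TPM + 1), 4504 and 3164 by DESeq2 and 4309 and 3218 by limma-voom.

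Deviations of libraries with the same replicate number correlated over 0.1 in 7 of 18 pairs (-0.277 to 0.436), and 9 of the 18 correlated best with their own number. All 3 pairs did so only for wild-type contralateral and peri-infarct tissue, where the replicate block gave 553 genes. Same-numbered libraries of the 2 genotypes, which cannot be 1 animal, correlated over 0.1 in 4 of 9 pairs. Whether a number marks 1 animal therefore stays open for every group. With the replicate block the wild-type core against border called 0 genes (5138 at an unadjusted p under 0.05) and the mean 19. With a random block limma-voom called 0 in contralateral tissue (441 at an unadjusted p under 0.05). It called 177 and 0 in the wild-type border and core against border (6698 at an unadjusted p under 0.05), 380 and 52 in the knockout and 23 for the mean. The replicate block in edgeR moved no other count by over 1.5 times.

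With each library left out in turn the genotypes gave 0 to 6, 0 to 18 and 2 to 472 genes, the wild type 0 to 3016, 4426 to 8337 and 0 to 5421, the knockout 56 to 3296, 2401 to 8854 and 0 to 6190, the differences of responses 0 (112, 366 and 286 at an unadjusted p under 0.05 with all libraries) and the mean 13 to 1151. With an estimated correlation 0 lists shifted in every comparison but the knockout border, with 1. With each library left out the genotypes shifted 10 to 19, 11 to 16 and 13 to 17 lists and the mean 12 to 16, and without the wild-type core library of replicate 3 the difference of responses of core against border shifted 23. Without that library 8 lists turned direction between the genotypes in the core, 8 in the difference of responses of core against contralateral tissue and 6 in that of core against border. The interferon list turned in the difference of responses at the border without replicate 1 of either contralateral group. The Trem2 level in each library gave a mean log2 difference of -5.33 in log2 CPM and -5.02 in log2(TPM + 1).

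For single genes named in the text, 2329 values over all settings kept direction and side of the threshold, 177 came to pass it, 496 no longer passed and 9 turned direction. These 9 belong to the genotype comparison in the core and to 3 genes that did not pass there in edgeR with all libraries. Htr2a, at -0.95 with all libraries, was at 0.0914 by limma-voom, 0.0909 with the random block and 0.199 on log2(TPM + 0.1). Hs3st2, at -0.91, was at 1.51 by limma-voom and with the random block, 0.0789 on log2(TPM + 1) with and without the TPM minimum, and 1.07 on log2(TPM + 0.1). Oasl1, at 0.39, ranged from -0.111 to 1.93 with each library left out.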

Other observations

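The comparisons in this part were chosen after the results were seen. Some cytokine, chemokine and neutrophil genes were higher in the knockout core once the wild-type core library of replicate 3 was left out. The 2 wild-type core libraries that remain had lower scar scores (1.5 and 1.59) than the knockout ones (1.94 to 2.65). The amount of lesion in the pieces and genotype therefore cannot be told apart. Of 19 cytokine and chemokine genes 4 rose (9 adjusted over the list alone, median 0.97, camera adjusted p = 1.6e-05, and adjusted p = 0.24 with an estimated correlation). Of 8 neutrophil genes 2 rose (4 adjusted over the list alone, median 1.73, adjusted p = 0.39 with an estimated correlation). In the same fit the reactive astrocyte list rose more from contralateral tissue to core in the knockout, where its contralateral score was lower (-1.52 against -1.07), with 0 of 21 over all genes in edgeR, 11 adjusted over the list alone and a median difference of 0.89 (camera adjusted p = 4.3e-11, and adjusted p = 0.17 with an estimated correlation). The score of 5 T and NK cell genes was higher in the knockout by 0.586 over the regions (2-sided exact permutation p = 0.0138, 0.0851 adjusted over 37 lists), and by 0.725 without that library (0.0148 adjusted, permutation).

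Outside the neighbourhood of Trem2, 23 genes were lower and 12 higher in the knockout at an unadjusted p under 0.05 in all 3 regions. Of the 23, 5 are disease-associated microglia genes, Spp1, Gpnmb, Cst7, Itgax and Clec7a, members of the list already described as lower. The chemokine Ccl4 was at -3.80 ± 1.18, -1.48 ± 0.64 and -1.72 ± 0.60 in contralateral, peri-infarct and core tissue and its relative Ccl3 at -1.85 ± 0.75, -1.17 ± 0.52 and -1.17 ± 0.50, and neither passed in any region.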
